A study of Mus musculus with 8 samples.

How the data were processed

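Gene expression was measured by RNA sequencing in ear epidermal sheets from 8 mice. Sheets were lifted off split ear skin after an overnight trypsin float and lysed with bead beating. Libraries were made per the labels with the SMART-Seq v4 kit, which copies poly-adenylated RNA to full-length cDNA and amplifies it by PCR, followed by Nextera tagmentation and paired-end sequencing on a NovaSeq. This chemistry keeps neither the strand nor molecular identifiers, so overlapping genes on opposite strands share reads and PCR copies cannot be told from separate molecules. Standard errors therefore describe the spread between mice and the counting error together.

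The deposited values are raw counts per Ensembl mouse gene, in 2 lane columns for each of the 8 libraries. The authors' processing notes name STAR 2.4.2a, Picard 1.139 and HTSeq 0.6.1p1 and the builds GRCm38.p5 and GRCh38, without saying what each tool did. The annotation release, the counting options and any read filter are not given in the sources used here. Each value was checked to be a whole number, and the 2 lanes of a library were summed. The summed counts averaged 70820780 per library, above the average read number that the labels state. In 15 of the 16 lane columns more genes held 4 counts than 3. Among genes with at least 20 counts, the chi-square of the split between lanes was 2.48 to 2.75 per gene, where independent reads would give about 1. A count is therefore not taken as an independent fragment.

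The files hold 51912 gene identifiers, of which 51633 matched a symbol in the reference tables and 51719 a position in GENCODE mouse release M21 on GRCm38. No count was recorded in any library for 23541 of them. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (a minimum count of 10, scaled to the library size, and a total of 15), which left 16512. Libraries were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood model was fitted with robust dispersions and the group as its only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided quasi-likelihood test, with no fold threshold. Log2 changes are A20KIKO minus A20WT. Normalised counts (CPM, scaled to the library total and its TMM factor) are given as mean ± SD over 4 libraries, log2 changes with an approximate standard error (SE). This SE was derived from the test, as the absolute log2 change divided by the square root of its F statistic. Gene lists were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01, over all lists with at least 5 tested members, and again with a correlation estimated for each list. A list's level in a library is the mean over its tested members of log2 CPM, at a prior count of 2, minus the mean of the A20WT libraries. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 read the files and drew the plots.

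Groups were taken from the labels alone. The groups, the test, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The lists were 36 gene lists and 23 cell type lists, 59 in all. The sex-linked list was kept for its values, and 3 lists had fewer than 5 tested members, so 55 were tested. The rule named Tnfaip3, Krt5 and Krt14. It added the 8 genes with the highest and the 8 with the lowest log2 change among those that were called, had a mean of at least 5 CPM and did not overlap between the groups. Of each list it named up to 3 called members with the smallest adjusted p, or, where none was called, up to 2 members with the highest mean. A gene named outside this rule is marked in the text as chosen after its values were seen.

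The alternatives were other size factors, no count filter and a stricter one (5 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom with and without sample weights, non-robust dispersions, an adjusted p under 0.01, a test against a 1.5-fold change, counts thinned to the smallest library, the replicate number as a block, and leaving out each library in turn. For the lists they were an estimated correlation, the fry test, other size factors, the block, each library left out, and genes found in a single list. Each lane alone was added after the data were seen. The pipeline was tested on simulated counts of 16512 genes modelled on these libraries, with 200 genes set to change and 5 lists raised. It recovered 9 of 66 genes changed 1.5-fold (13.6%), 34 of 64 changed 2-fold (53.1%) and 52 of 60 changed 4-fold (86.7%), with 0 in the wrong direction. Of its 105 calls, 10 were unchanged genes (9.52%). It recovered 5 of the 5 lists raised 1.5-fold and called 1 of the 46 lists without a raised gene. The simulated genes varied independently of each other, while the estimated correlation in the type I interferon list was 0.88. The simulation therefore does not show how often camera calls lists whose members vary together.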

Results

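RNA from ear epidermal sheets of 8 mice was sequenced, 4 labelled A20KIKO and 4 labelled A20WT, with each library from a different animal. A20, the product of Tnfaip3, is a ubiquitin-editing enzyme that restrains NF-kB signalling and cell death downstream of TNF and Toll-like receptors. By the labels, both groups carried conditional Tnfaip3 alleles, and the A20KIKO mice also carried a tamoxifen-inducible Cre recombinase driven by the promoter of Krt5, a keratin gene of basal keratinocytes. All animals were 8 weeks old, were given 1 mg of tamoxifen per injection in 2 injections and were killed 7 days after the first. The comparison of A20KIKO with A20WT libraries therefore addresses which epidermal transcripts differ 7 days after the first tamoxifen injection. By the labels the difference is an induced keratinocyte deletion of A20, with the presence of the Cre itself part of it. Summed counts per library ranged from 40451075 (A20KIKO mouse 3) to 89624373 (A20WT mouse 1), with 68501083 ± 23344215 (SD, n = 4) in the A20KIKO and 73140478 ± 17004239 (SD, n = 4) in the A20WT libraries. Counts of Xist lay between 804 and 2146 in each library, and 4 genes of the Y chromosome had 0 counts in each.

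Tnfaip3 itself was higher in the libraries labelled A20KIKO, the opposite of what the label names. Tnfaip3 (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657 in GRCm38) had 74.0 ± 17.3 CPM (SD, n = 4) in the libraries labelled A20KIKO and 16.5 ± 2.65 CPM (SD, n = 4) in those labelled A20WT. This is a 4.48-fold rise (log2 change 2.16, SE 0.18, edgeR adjusted p = 8.36e-05), and each of the 4 libraries labelled A20KIKO lay above each of the 4 labelled A20WT. The files give a single count for the whole gene, which includes reads from exons outside the deleted part, and the deleted exons are not given in the sources used here, so this count does not test the deletion. Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) fell from 6230 ± 575 to 3510 ± 133 CPM (SD, n = 4 each), a log2 change of -0.83 (SE 0.12, edgeR adjusted p = 0.00272). Its partner keratin Krt14 had 16900 ± 2530 CPM in the libraries labelled A20KIKO and 20600 ± 5100 CPM in those labelled A20WT (SD, n = 4 each), and this difference did not pass the test (edgeR adjusted p = 0.537). Tested against a change of at least 1.5-fold, the fall of Krt5 did not pass (adjusted p = 0.338), with adjusted p of 0.000448 to 0.0156 in the other settings of edgeR and limma-voom.

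**Figure D1:**
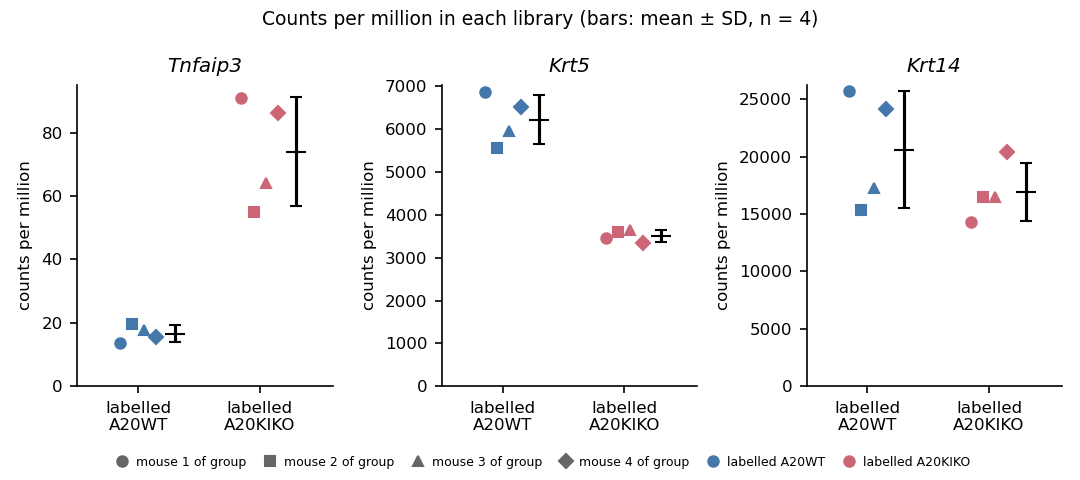
Normalised count (CPM) of Tnfaip3, Krt5 and Krt14 in each of the 8 libraries (points, shaped by mouse number within the group), on linear axes from 0, with the mean and SD of each group of 4 (bars). Tnfaip3 lay at 55 CPM or more in the libraries labelled A20KIKO and at 19.6 CPM or less in those labelled A20WT, Krt5 was lower in each library labelled A20KIKO, and the Krt14 values of the groups overlapped.

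Among changed genes with a mean of at least 5 CPM and no overlap between the groups, the widest changes were rises, and 7 of the 8 highest genes were members of the type I interferon list. Rsad2, which encodes the antiviral enzyme viperin, rose from 0.049 ± 0.0281 to 34.7 ± 24.9 CPM (SD, n = 4 each), a log2 change of 9.36 (SE 0.91, edgeR adjusted p = 0.00227). Ifit1, an antiviral RNA-binding protein, rose from 0.722 ± 0.233 to 171 ± 92.7 CPM (log2 change 7.89, SE 0.55, adjusted p = 0.000514). Oasl2, a member of the oligoadenylate synthetase family, rose from 1.58 ± 0.592 to 118 ± 65.1 CPM (log2 change 6.23, SE 0.57, adjusted p = 0.00184). Ifi44, Ifit3b, Ifit3, Rtp4 and the predicted antisense gene Gm20234 completed the 8 highest of these, with log2 changes of 8.34, 7.11, 6.58, 6.32 and 6.14. Without strand information, reads of Gm20234 were not separable from those of a gene on the opposite strand. These folds start from near 0: the 4 libraries labelled A20WT together held 15 counts of Rsad2, 13 of Ifi44 and 22 of Ifit3b. Among the falls, Ccdc80, an extracellular matrix protein, went from 20.4 ± 3.98 to 4.31 ± 1.43 CPM (log2 change -2.25, SE 0.23, adjusted p = 0.000454). Igfbp3, a secreted binding protein of insulin-like growth factors, went from 459 ± 49.4 to 175 ± 30.3 CPM (log2 change -1.39, SE 0.14, adjusted p = 0.00037). Cyp2g1, Mrgprb11-ps, Wnk4, Kcnj16, Bco1 and Btc completed the 8 lowest of these, with log2 changes of -2.35, -1.72, -1.60, -1.57, -1.56 and -1.38. Each of these 16 genes separated the 4 libraries of a label from the 4 of the other.

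In all, 576 of 16512 tested genes changed (3.49%), 401 higher and 175 lower in the libraries labelled A20KIKO, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 287 rose and 87 fell at least 2-fold, and 143 rose and 25 fell at least 4-fold. At an unadjusted p under 0.05 there were 2543 genes. The groups did not overlap in 1745 genes (10.6% of those tested, where chance gives 2.86%), 563 of them among the changed. The biological coefficient of variation was 26.3%. Of the changed genes, 116 were members of a fixed list, 50 of them in the type I interferon and interferon-gamma lists, and 460 were in no list. The count was 348 without A20KIKO mouse 1 (256 higher, 92 lower) and 355 without A20WT mouse 3 (254 higher, 101 lower), and the fallen genes numbered 110 without A20KIKO mouse 3. Adjusted p of 5 of the 16 genes named above reached 0.05 or more when a single library was left out: Ifi44 without A20WT mouse 1, 2 or 4 (0.0502 to 0.0619), Ifit3b without A20WT mouse 1, 2 or 3 (0.0582 to 0.0742), Cyp2g1 without A20KIKO mouse 3 or A20WT mouse 1, 2 or 3 (0.0511 to 0.0861), Wnk4 without A20KIKO mouse 1 or A20WT mouse 2 (0.0503 to 0.0543) and Btc without A20KIKO mouse 3 or A20WT mouse 1, 2 or 3 (0.0564 to 0.109).

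Each of the 30 type I interferon-stimulated genes of the fixed list rose, with a median log2 change of 4.54, or 23.3-fold. By edgeR's quasi-likelihood test 30 of 30 passed over all tested genes and 30 adjusted over the list alone, and camera placed the list above other genes (adjusted p = 1.37e-122). With an estimated correlation the list's adjusted p = 0.103. Isg15, a ubiquitin-like protein that is conjugated to other proteins, rose from 5.76 ± 1.43 to 159 ± 65.5 CPM (SD, n = 4 each), a log2 change of 4.79 (SE 0.32, adjusted p = 8.36e-05). Usp18, the protease that removes Isg15 and dampens interferon receptor signalling, rose 16.6-fold (log2 change 4.05, SE 0.27), and Xaf1, an interferon-induced regulator of apoptosis, rose 13.7-fold (log2 change 3.78, SE 0.26). Of 26 interferon-gamma-responsive and MHC class I genes, 20 rose and 0 fell, 25 rose adjusted over the list alone, and the median log2 change was 1.57 (camera adjusted p = 1.75e-51, and adjusted p = 0.192 with an estimated correlation). Irf1, a transcription factor of the interferon response, rose from 15.7 ± 3.46 to 60.3 ± 15.9 CPM (log2 change 1.95, SE 0.21, adjusted p = 0.00058). Tap1, a subunit of the peptide transporter of antigen presentation, rose from 111 ± 9.39 to 251 ± 42.5 CPM (log2 change 1.17, SE 0.13, adjusted p = 0.000924), and the guanylate-binding protein Gbp6 rose 9.24-fold (adjusted p = 0.0011). The level of the type I list was 3.36 to 5.30 log2 units in the libraries labelled A20KIKO and -0.35 to 0.23 in those labelled A20WT. The level of the list of markers shared by leukocytes was 0.48 ± 0.34 and 0 ± 0.20 (SD, n = 4 each). That of the monocyte and macrophage list was 1.70 ± 0.80 and 0 ± 0.25, with a lowest level of 0.76 in the libraries labelled A20KIKO and a highest of 0.28 in the others. For the leukocyte list these levels were 0.20 and 0.20, so the groups met at the precision given.

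Genes of NF-kB feedback, the TNF superfamily, chemokines and cell death rose in part. The monocyte and macrophage list moved alongside (median log2 change 2.04), and the cells behind these rises were not resolved. Of 20 NF-kB feedback and target genes, 7 rose and 0 fell by edgeR's quasi-likelihood test, 17 rose adjusted over the list alone, and the median log2 change was 0.80 (camera adjusted p = 3.24e-16, and adjusted p = 0.27 with an estimated correlation). Icam1, an adhesion molecule for leukocytes, rose from 23.2 ± 7.1 to 107 ± 22.3 CPM (log2 change 2.20, SE 0.21, adjusted p = 0.000265). The NF-kB subunits Relb and Nfkb2 rose 1.87-fold and 1.80-fold (adjusted p = 0.00107 and 0.0119). The number of risen members was 4 without A20KIKO mouse 1, A20WT mouse 2 or A20WT mouse 3. Of 18 TNF superfamily ligands and receptors, 5 rose, 7 adjusted over the list alone (camera adjusted p = 3.59e-07, and adjusted p = 0.241 with an estimated correlation), and 3 rose without A20KIKO mouse 1, A20WT mouse 3 or A20WT mouse 4. The death receptor Fas rose from 9.54 ± 1.16 to 19.1 ± 0.51 CPM (log2 change 1.00, SE 0.13, adjusted p = 0.0014) and the TNF receptor Tnfrsf1b rose 2.73-fold (adjusted p = 0.00538). The ligand Tnf rose from 1.27 ± 0.393 to 5.16 ± 3.25 CPM (log2 change 2.04, SE 0.39, edgeR adjusted p = 0.0121, and 0.0678 without A20WT mouse 1). It had 9.95 CPM in A20KIKO mouse 4 and 2.94 to 4.36 CPM in A20KIKO mice 1 to 3. Of 20 partners of A20 and ubiquitin editors, 3 rose, Tnip1, Tnip3 and Birc3, and the list did not pass (camera adjusted p = 0.0984). These 3 genes are also members of the NF-kB list, and with genes found in no other list camera gave an adjusted p = 0.85. Adjusted p was 0.0517 to 0.0522 for Tnip1 without A20KIKO mouse 1 or A20WT mouse 3, 0.0767 to 0.145 for Tnip3 without A20KIKO mouse 1 or 3 or A20WT mouse 1, 2 or 4, and 0.0949 to 0.158 for Birc3 without A20KIKO mouse 1 or 4 or any A20WT mouse. The list passed without A20KIKO mouse 2 (0.0435) or A20WT mouse 3 (0.0464).

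Of 18 chemokines, 7 rose and 1 fell, with 11 and 2 adjusted over the list alone (camera adjusted p = 3.96e-14, and adjusted p = 0.241 with an estimated correlation). Cxcl10, which attracts activated T cells, rose from 1.68 ± 0.378 to 43.9 ± 25.8 CPM (SD, n = 4 each), a log2 change of 4.71 (SE 0.47, edgeR adjusted p = 0.00169). Ccl5, another chemokine for T cells and monocytes, rose 23.8-fold (adjusted p = 0.00162) and Cxcl16, the ligand of Cxcr6, rose 2.08-fold (adjusted p = 0.00139). The falling member was Cx3cl1, the ligand of Cx3cr1, at 57.6 ± 6.82 and 37.1 ± 2.93 CPM (log2 change -0.64, adjusted p = 0.0116). It was named after its value was seen, and its adjusted p was 0.0505 without A20KIKO mouse 1. Of 29 cell death and inflammasome genes, 7 rose, 11 adjusted over the list alone (camera adjusted p = 2.43e-07, and adjusted p = 0.27 with an estimated correlation), and 4 rose without A20WT mouse 4. Bid, which links death receptors to mitochondria, rose from 17.0 ± 1.89 to 36.4 ± 3.56 CPM (log2 change 1.10, SE 0.13, adjusted p = 0.000927), and Gsdmd, the pore-forming protein of pyroptosis, rose 2.72-fold (adjusted p = 0.00313).

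**Figure D2:**
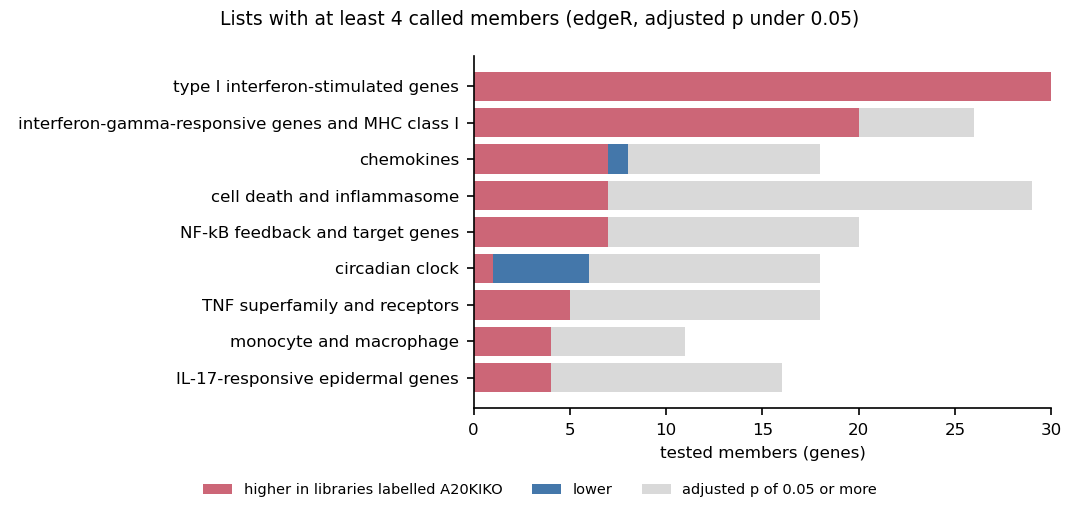
Number of tested members (x axis, genes) that were higher, lower or at an adjusted p of 0.05 or more (bar segments) in each list with at least 4 called members by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 30 type I interferon-stimulated genes were higher, and 5 of the 18 circadian clock genes were lower.

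Genes of the epidermal response to IL-17 rose in part, and A20KIKO mouse 4 stood apart from the other libraries in them. Of 16 tested members, 4 rose and 0 fell by edgeR's quasi-likelihood test, 6 rose adjusted over the list alone, and the median log2 change was 3.44 (camera adjusted p = 8.98e-10, and adjusted p = 0.425 with an estimated correlation). Only 4 of the 16 tested members were in no other list, fewer than the 5 needed to test the list with such genes. Ccl20, for one, was also in the chemokine list. The median was 0.77 without A20KIKO mouse 4, and 2 members rose without A20WT mouse 1, 2 or 3. Ccl20, a chemokine for Ccr6-bearing lymphocytes, rose from 4.34 ± 1.06 to 111 ± 60.9 CPM (log2 change 4.67, SE 0.47, adjusted p = 0.00184). Steap4, a metalloreductase, rose from 42.6 ± 8.45 to 109 ± 18.3 CPM (log2 change 1.36, SE 0.17, adjusted p = 0.00114). The level of the list was 4.35 in A20KIKO mouse 4 and 0.61 to 1.44 in the other libraries labelled A20KIKO. S100a8 and S100a9, the subunits of calprotectin, and the stress keratins Krt6b and Krt16 were named after their values were seen. S100a8 had 947 CPM in A20KIKO mouse 4, against 2.7 to 18.6 in A20KIKO mice 1 to 3 and 0.396 to 8.32 in the libraries labelled A20WT, and did not pass the test (adjusted p = 0.329). S100a9 had 1900 CPM, Krt6b 2820 CPM and Krt16 3370 CPM in that mouse, with adjusted p = 0.324, 0.608 and 0.624. The stress keratins were next highest in A20WT mouse 4, with 303 CPM of Krt6b and 823 CPM of Krt16. A20KIKO mice 1 to 3 had 22.4 to 147 and 197 to 545 CPM. Some markers of other cells were also high in A20KIKO mouse 4. Cxcr2, the 1 tested of 18 neutrophil markers, had 48.6 CPM (9.54 to 12.5 in A20KIKO mice 1 to 3, adjusted p = 0.52). It had 3.3 to 13 CPM in the libraries labelled A20WT. Hdc, 1 of 2 tested members of the mast cell, basophil and eosinophil list, had 25.8 CPM (0.381 to 1.53 in A20KIKO mice 1 to 3, adjusted p = 0.184). The other member, Mrgprb2, had 0.66 CPM in A20KIKO mouse 4 and a log2 change of -0.55 (adjusted p = 0.472). The monocyte and macrophage list had its highest level in that mouse, 2.59. The cells behind the S100a8 and S100a9 counts were not resolved. Krt6b went from a log2 change of 3.07 to -0.42 without A20KIKO mouse 4.

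The lists that share this epidermal response moved with the same library. They are not independent of the IL-17 list, since the antimicrobial list also holds S100a8 and S100a9, and 10 of its 17 tested members were in no other list. Of 17 antimicrobial protein genes, 1 rose and 1 fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 8.36e-05, and adjusted p = 0.466 with an estimated correlation). The median log2 change was 1.90, and 0.76 without A20KIKO mouse 4, and 2 members rose without A20KIKO mouse 2, 3 or 4 or A20WT mouse 4. Its changed members were the peptidoglycan recognition protein Pglyrp3, which rose 2.75-fold (edgeR adjusted p = 0.0102, and 0.0606 to 0.087 without A20WT mouse 1 or 2), and Rnase4, a secreted ribonuclease (log2 change -0.44, adjusted p = 0.0492, and 0.052 to 0.166 without any single library except A20WT mouse 4). Of 22 wound-associated keratinocyte genes, 1 rose and 1 fell, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.000749, and adjusted p = 0.601 with an estimated correlation), and without A20KIKO mouse 4 the list did not pass (0.11) and its median went from 0.98 to 0.10. These were EGF receptor ligands: Epgn rose from 1.35 ± 0.285 to 17.6 ± 6.96 CPM (log2 change 3.71, SE 0.30, adjusted p = 8.36e-05), and Ereg fell from 28.8 ± 4.57 to 15.3 ± 3.51 CPM (log2 change -0.91, SE 0.17, adjusted p = 0.0123). Of 19 squamous serpins and stefins, 2 rose, 5 adjusted over the list alone (camera adjusted p = 0.000628, and adjusted p = 0.425 with an estimated correlation). Its median was 0.46, and 0.18 without A20KIKO mouse 4, and 1 member rose without A20KIKO mouse 4, A20WT mouse 3 or A20WT mouse 4, against 4 without A20KIKO mouse 2. Serpinb6c rose 3.55-fold (adjusted p = 0.00049). Of 13 small proline-rich proteins, which build the cornified envelope, 0 passed and the list did not pass (camera adjusted p = 0.183). Sprr2d had 1360 CPM in A20KIKO mouse 4, 18.3 to 27.8 in A20KIKO mice 1 to 3 and 3.14 to 67 in the A20WT mice. Its log2 change of 3.68 became -0.37 without A20KIKO mouse 4. The IL-23 and IL-17 cytokine list passed (camera adjusted p = 0.0181, and adjusted p = 0.425 with an estimated correlation) with 0 of 10 members changed. It did not pass without A20KIKO mouse 4 (0.237), where its median went from 0.69 to 0.18. The IL-6 and IL-20 family list passed narrowly (0.0477, and adjusted p = 0.425 with an estimated correlation), but not without A20KIKO mouse 4 (0.11) or A20WT mouse 1 (0.116). It was placed higher, and did not pass with genes found in no other list (0.127). Of its 15 members 1 rose and 1 fell, with 6 and 3 adjusted over the list alone, and 2 rose without A20KIKO mouse 2 or A20WT mouse 4. The cytokine Lif rose from 1.37 ± 0.514 to 3.31 ± 0.627 CPM (log2 change 1.27, adjusted p = 0.0351, and 0.0555 to 0.128 without A20KIKO mouse 1, 3 or 4 or A20WT mouse 1 or 3), and the receptor subunit Il20ra fell (log2 change -0.72, adjusted p = 0.00628).

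**Figure D3:**
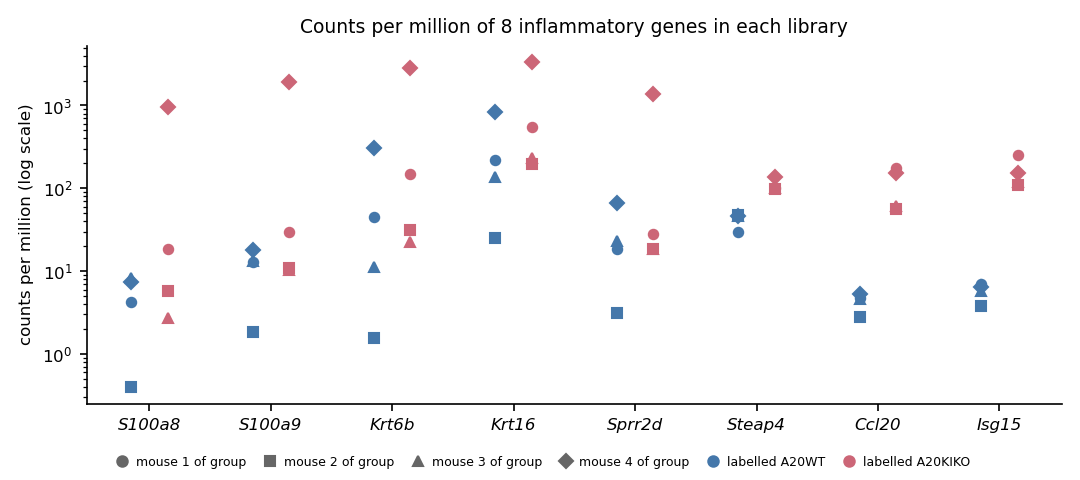
Normalised counts (CPM) on a log axis of 8 genes in each library, shaped by mouse number and coloured by label. A20KIKO mouse 4 was the highest library for S100a8, S100a9, Krt6b, Krt16 and Sprr2d, with A20WT mouse 4 next for Krt6b, Krt16 and Sprr2d. Steap4, Ccl20 and Isg15 were higher in each library labelled A20KIKO.

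Few of the listed genes of keratinocyte identity and barrier passed the test, where 3.49% of all tested genes did. The simulation recovered 13.6% of genes changed 1.5-fold, so small changes among the others are not excluded. Of 19 basal keratinocyte and hemidesmosome genes, 0 rose and 1 fell, Krt5, and the list did not pass (camera adjusted p = 0.608). Its median log2 change was 0.04, and -0.02 to 0.09 without single libraries. Its mean was -0.02, and camera's direction was down. Of 30 suprabasal differentiation and barrier genes, 0 rose and 2 fell, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.946). The fallen genes were the filaggrin family member Flg2 at 172 ± 38.6 and 91.9 ± 22.1 CPM (log2 change -0.90, edgeR adjusted p = 0.0292) and the keratin Krt77 at 621 ± 129 and 349 ± 77.9 CPM (log2 change -0.83, adjusted p = 0.0259, with overlapping groups). Without A20KIKO mouse 3 or A20WT mouse 1, 2 or 3 adjusted p of Flg2 was 0.0753 to 0.123, and without A20KIKO mouse 2, 3 or 4 or A20WT mouse 1, 2 or 4 that of Krt77 was 0.0632 to 0.0866. In the list 1 member rose without A20KIKO mouse 4 or A20WT mouse 3. The 21 late cornified envelope genes were placed lower by camera (adjusted p = 8.36e-05, and adjusted p = 0.466 with an estimated correlation), with 0 members changed over all tested genes, 5 lower adjusted over the list alone, and a median log2 change of -0.45, or -0.24 without A20WT mouse 1. Without A20WT mouse 2, 4 members fell. Lce1m had 1830 ± 821 CPM in the libraries labelled A20WT and 950 ± 400 CPM in those labelled A20KIKO (SD, n = 4 each, adjusted p = 0.252). Adhesion and tight junction genes (0 of 25 changed, 0.0984), ceramide and barrier lipid synthesis (0 of 24, 0.3), the IL-1 family (0 of 15, 0.552) and WNT, BMP and Notch genes (1 of 25 lower, 0.938) did not pass as lists. Of the WNT, BMP and Notch genes 0 fell without A20KIKO mouse 1 or 4 or A20WT mouse 3 or 4, and 2 fell without A20WT mouse 1. In that list 1 gene rose without A20KIKO mouse 4 or A20WT mouse 2. Without A20WT mouse 2 or 3 the adhesion list did (0.0161 and 0.0428).

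Genes of the circadian clock fell in part. Of 18 members, 5 fell and 1 rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000498, and adjusted p = 0.295 with an estimated correlation). Dbp, a transcription factor whose level follows the time of day, fell from 146 ± 16.4 to 68.5 ± 12.5 CPM (SD, n = 4 each), a log2 change of -1.09 (SE 0.14, edgeR adjusted p = 0.00139). The clock gene Per3 fell from 47.7 ± 5.77 to 27.4 ± 2 CPM (log2 change -0.80, SE 0.12, adjusted p = 0.00309), and Nfil3, a repressor that opposes Dbp, rose 2.46-fold (adjusted p = 0.00107). The list's median log2 change was -0.26, and -0.12 without A20WT mouse 2. The other falling members, Hlf, Bhlhe41 and Nr1d1, were named after their values were seen, with log2 changes of -0.80, -0.89 and -0.62 (adjusted p = 0.00325, 0.00653 and 0.0176). Without A20KIKO mouse 1 or 2 or A20WT mouse 3 or 4 adjusted p of Nr1d1 was 0.0523 to 0.0751. The time of day of collection is not given in the sources used here.

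Lists of proliferation passed without a changed member. Camera placed 24 genes of the G2/M phase higher (median log2 change 0.34, adjusted p = 9.16e-06, and adjusted p = 0.425 with an estimated correlation), with 0 changed, 7 higher adjusted over the list alone, and 2 higher without A20KIKO mouse 2 or A20WT mouse 1. The 24 DNA replication genes (median 0.13, adjusted p = 0.0486, and adjusted p = 0.425 with an estimated correlation) did not pass without A20KIKO mouse 1, 3 or 4 or A20WT mouse 2 or 3 (0.0534 to 0.117), or with genes found in no other list (0.0524), and had 1 higher member without A20WT mouse 4. The mitotic cyclin Ccnb1 had 71.8 ± 13.7 and 59.1 ± 5.05 CPM (SD, n = 4 each, edgeR adjusted p = 0.38). Glycolysis and hypoxia genes (0 of 22 changed) had a median log2 change of 0.30, and 0.14 with 2 changed members without A20KIKO mouse 4 (camera adjusted p = 0.000628, and adjusted p = 0.549 with an estimated correlation). Mitochondrially encoded transcripts (0 of 14 changed, median -0.40, and -0.25 without A20WT mouse 3) passed as lower (adjusted p = 0.0113, and adjusted p = 0.644 with an estimated correlation), but not without A20KIKO mouse 3, A20WT mouse 1 or A20WT mouse 3 (0.0602 to 0.146). Ribosomal proteins (0.123), nuclear-encoded oxidative phosphorylation (0.428), the unfolded protein response (0.158), immediate-early and heat shock genes (0.713), cholesterol synthesis (0.361), fatty acid metabolism (0.279), retinoid metabolism (0.077), eicosanoid synthesis (0.0797), oxidant and NRF2 genes (0.653) and Toll-like receptor signalling (0.133) did not pass. Single members did: Tlr2, a receptor for bacterial lipoproteins, rose 6.19-fold (adjusted p = 0.00391), the retinol dehydrogenase Rdh16 rose 2.97-fold (adjusted p = 0.00137), the prostaglandin E synthase Ptges rose 1.76-fold (adjusted p = 0.0123), and the glutathione transferase Gstm1 fell (log2 change -0.82, adjusted p = 0.00604). Some of these lists passed when a single library was left out. These were ribosomal proteins without A20KIKO mouse 1, A20KIKO mouse 2 or A20WT mouse 2 (0.0484, 0.00974 and 1.67e-05), oxidative phosphorylation without A20KIKO mouse 3 or A20WT mouse 1 (0.00222 and 0.000364), fatty acid metabolism without A20KIKO mouse 3 (0.0488), retinoid metabolism without A20KIKO mouse 1 or 4 or A20WT mouse 1 or 4 (0.0388 to 0.047), eicosanoid synthesis without A20KIKO mouse 2 or 3 or A20WT mouse 4 (0.0259 to 0.0499) and Toll-like receptor signalling without A20KIKO mouse 2 or A20WT mouse 2 (0.00638 and 0.0272).

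Among cell type lists, monocyte and macrophage markers rose in part. Of 11 tested, 4 rose and 0 fell, 6 adjusted over the list alone (camera adjusted p = 7.12e-11, and adjusted p = 0.243 with an estimated correlation), with a median log2 change of 2.04, and 1.34 without A20KIKO mouse 4, while 9 rose without A20KIKO mouse 2. The complement component genes C1qa, C1qb and C1qc rose 4.56-fold, 13.6-fold and 9.82-fold (edgeR adjusted p = 0.00184, 0.00227 and 0.00272), from 1.36 ± 0.439, 0.556 ± 0.193 and 0.386 ± 0.175 CPM in the libraries labelled A20WT (SD, n = 4). The fourth was the monocyte marker Ly6c2, named after its value was seen (log2 change 3.81, adjusted p = 0.00334). The 12 markers shared by leukocytes had a median log2 change of 0.41 with 0 changed, and 1 higher without A20KIKO mouse 2 or A20WT mouse 1 (camera adjusted p = 0.000118, and adjusted p = 0.425 with an estimated correlation). Arhgdib among them had 158 ± 12 and 118 ± 13.3 CPM (adjusted p = 0.0658, and 0.0186 without A20WT mouse 1). Langerhans cell markers (1 of 13 changed, 0.0123), migratory dendritic cell markers (2 higher and 1 lower of 11, 0.0411) and alpha-beta T cell markers (0 of 14, 0.0123) passed as higher, and with an estimated correlation adjusted p = 0.486, 0.425 and 0.601. Langerhans markers did not pass without A20WT mouse 2 (0.0681) and had 0 changed members without A20KIKO mouse 1, A20KIKO mouse 4 or A20WT mouse 3, dendritic cell markers without A20KIKO mouse 1, 2 or 4 or A20WT mouse 2 or 3 (0.0528 to 0.121) or with genes found in no other list (0.296), and T cell markers without A20KIKO mouse 4 (0.128) or A20WT mouse 2 (0.104, with 1 member lower). The lower dendritic cell marker, Cacnb3, lost its call without any single library (0.0602 to 0.158). The list of resident gamma-delta T cells of the epidermis did not pass (0 of 14, 0.946), and their receptor subunit Cd3g had 38.5 ± 1.48 and 38.9 ± 5.93 CPM.

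Camera placed lists of connective tissue and cartilage markers lower. Of 11 fibroblast markers, 0 rose and 1 fell, 4 lower adjusted over the list alone, with a median log2 change of -1.35 (camera adjusted p = 7.42e-06, and adjusted p = 0.295 with an estimated correlation). The collagen Col6a1 fell from 7.91 ± 1.94 to 3.28 ± 1.16 CPM (SD, n = 4 each, log2 change -1.27, edgeR adjusted p = 0.0168), and the falling members numbered 5 without A20KIKO mouse 2 and 3 without A20KIKO mouse 3. Chondrocyte markers, of the ear cartilage, had a median of -1.65 (adjusted p = 2.1e-05, and adjusted p = 0.425 with an estimated correlation), with 1 of 8 fallen and 6 adjusted over the list alone. That member was the collagen Col11a2 (adjusted p = 0.0395), at 0.054 to 0.131 without A20KIKO mouse 1, 2 or 3 or A20WT mouse 1, 3 or 4, and the falling members numbered 2 without A20KIKO mouse 2 or A20WT mouse 2. Erythrocyte markers (0 of 5 changed, median -0.86, and -1.41 with 4 members fallen without A20KIKO mouse 2, and 1 fallen without A20WT mouse 3) passed as lower (0.0113, and adjusted p = 0.425 with an estimated correlation). Melanocyte markers passed as higher (1 of 10 changed, adjusted p = 0.000252, and adjusted p = 0.425 with an estimated correlation), with 0 members changed without A20KIKO mouse 1 or 2 or A20WT mouse 1, 3 or 4, and 6 without A20KIKO mouse 4. Sebocyte markers passed as higher (2 of 14 changed, 0.0132, and adjusted p = 0.595 with an estimated correlation), but not without A20KIKO mouse 1 or 2 or A20WT mouse 4 (0.0729 to 0.203), and 1 member rose without A20KIKO mouse 1 or any A20WT mouse. Dgat2l6 among them, an acyltransferase, rose 2.29-fold (adjusted p = 0.000247). Hair follicle bulge (0.812), hair matrix (0.982), hair keratin-associated protein (0.83), Merkel cell (0.448), Schwann cell (0.358), skeletal muscle (0.287), endothelial (0.453) and adipocyte (0.079) markers did not pass, and the adipocyte list did without A20KIKO mouse 3 (0.0181) or A20WT mouse 4 (0.0197). Neutrophil, mast cell and B cell lists had 1, 2 and 3 tested members and were not tested as lists.

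**Figure D4:**
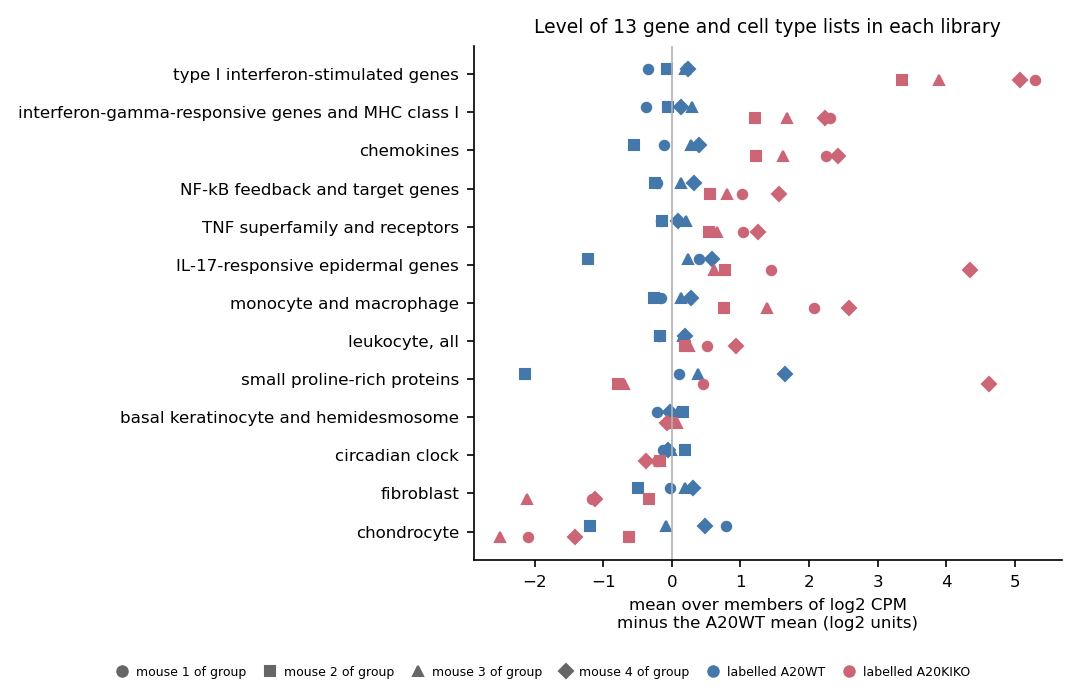
Level of 13 lists in each library (x axis, mean over members of log2 CPM minus the mean of the libraries labelled A20WT), shaped by mouse number and coloured by label. The type I interferon list lay at 3.36 or more in each library labelled A20KIKO, the IL-17 list lay at 4.35 in A20KIKO mouse 4, and the basal keratinocyte list lay between -0.07 and 0.07 in the libraries labelled A20KIKO.

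By camera at its preset correlation 28 of the 55 lists passed, 22 higher and 6 lower, and 0 passed with an estimated correlation, the lowest being adjusted p = 0.103 for the type I interferon list. The self-contained fry test called 10, of which 9 were among the 28. The first principal component, on log2 CPM, held 36.8% of the variance and separated the libraries by label. Correlations of log2 CPM across genes were 0.968 to 0.985 within a group and 0.950 to 0.977 between groups, with genes not being independent replicates.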

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

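The tests of explanations and the splits list by list were chosen after the results they bear on had been seen, and the numbers of genes and lists over other splits were planned.

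Tnfaip3 was 4.48-fold higher in the libraries labelled A20KIKO, against the direction of the label, and 3 explanations were weighed. A wrong label on single libraries would leave some values of the groups mixed. The lowest value among the libraries labelled A20KIKO (55 CPM) lay 35.4 CPM above the highest among those labelled A20WT (19.6 CPM), beyond the larger SD of 17.3 CPM, which argues against a wrong label on single libraries. An exchange of the labels of both groups as a whole would leave no values mixed, so this gap cannot test such an exchange, which stays open. Reads from exons outside the deleted part could not be separated, because the files give 1 feature for Tnfaip3, so a truncated transcript stays open. Tnfaip3 is itself an NF-kB target, and the NF-kB list had a median log2 change of 0.80, with levels of 0.56 or more in the libraries labelled A20KIKO and 0.32 or less in the others, so a rise of its transcription together with other NF-kB targets is a candidate explanation that a count of the deleted exons would test.

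Krt5, whose promoter drives the Cre, fell by 0.83 on the log2 scale, while Krt14 did not pass the test. Fewer basal keratinocytes would lower the other basal genes alike, but the other 18 members of the basal list had a median log2 change of 0.04 (SD 0.26), which argues against this. A difference in the genome around Krt5, such as flanking sequence of another strain, could place other changed genes nearby. An inserted Cre could lower Krt5 alone, and a count of its neighbours cannot test that. Within 5 Mb of Krt5, 6 of 138 tested genes were lower (4.35%, against 1.06% of all tested genes) and 3 were higher, and 1.97% of 15043 overlapping windows of the same size on other autosomes reached as high a share lower. Without single libraries 3 to 5 genes nearby were lower, and the share of windows was 2.49% to 17.2%, at 6.96% or more without A20KIKO mouse 2 or 3 or A20WT mouse 1 or 4, so such a difference stays open. The lower genes were Cacnb3, Faim2, Aqp5, Mettl7a1, Acvr1b and Krt77, and the higher ones Aaas, Hoxc5 and Pde1b, named after their values were seen except Cacnb3 and Krt77; Cacnb3, Acvr1b, Krt77 and Hoxc5 lost their calls in fits that left out single libraries (adjusted p up to 0.158, 0.139, 0.0866 and 0.125), and an effect of the A20 deletion on Krt5 itself was not tested and stays open.

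The interferon-stimulated genes rose in each library labelled A20KIKO, with a median log2 change of 4.54 (SD 2.04 between genes). A rise of leukocytes of all kinds, with their kinds and expression unchanged, would raise these genes no more than the shared leukocyte markers. The list of those markers had a median log2 change of 0.41 (SD 0.23), which argues against such a rise as the whole source. Leukocytes with raised expression of interferon-stimulated genes stay open. Shared markers started high in the libraries labelled A20WT (Arhgdib 118 ± 13.3 CPM) and Ifit1 near 0 (0.722 ± 0.233 CPM). Few added cells could therefore raise the lists by unlike folds. Monocyte and macrophage markers moved with the interferon-stimulated genes, with a median log2 change of 2.04 (SD 1.31) and levels of 0.76 to 2.59 in the libraries labelled A20KIKO and -0.26 to 0.28 in the others. The medians lay 2.50 apart, within the 3.35 of both SDs added, so more monocytes and macrophages as a source stay open. The log2 changes are of counts already scaled to the library totals, so setting totals against them cannot test depth. The highest log2 ratio of a total labelled A20KIKO to one labelled A20WT was 0.75, and the least changed member of the list had 1.43. On average the libraries labelled A20KIKO were not the deeper ones (68501083 against 73140478 counts). Interferon transcribed in the sheets stays open. Of 21 interferon genes, 2 lay above every library labelled A20WT in each library labelled A20KIKO, Ifnl2 and Ifnl3, named after their values were seen. Their lowest counts in a library labelled A20KIKO were 2 and 1, so 0 genes reached 3 counts in each. Whether keratinocytes or other cells account for the rise was not resolved, and the presence of the Cre is not separable from the deletion.

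The 8 libraries can be split into 4 and 4 in 35 ways. Under the real groups edgeR called 576 genes, and under the highest of the 34 others 0. So 1 of the 35 splits gave as many, the smallest share that 35 splits can give. A mixed split sets the difference between the labels inside its groups, which can widen their spread and hold calls down. For the number of lists passing camera chance was not excluded: the real groups gave 28, the highest other split 35, and 12 of the 35 splits gave as many. Splits that keep most libraries of a label together still hold part of the difference between the labels. The type I interferon list passed in 22 of the other splits, so their numbers of lists do not show what chance alone gives. List by list, 7 of the 28 had their smallest p under the real groups (type I interferon, interferon-gamma and MHC class I, NF-kB, TNF superfamily, chemokine, IL-17 and circadian clock lists), a share of splits under 0.05, and 21 did not.

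Gaps between libraries were measured on log2 CPM, and values are given in CPM. Of 364 groups of 4 values (127 genes and 55 lists in 2 groups each), 17 held a library whose gap to the nearest other, divided by the range of the group, exceeded Dixon's critical value for 4 samples, or 4.67%, where chance gives about 1 in 20. Among these A20KIKO mouse 4 appeared 5 times. It had 1360 CPM of Sprr2d (others of its group 18.3 to 27.8), 760 CPM of Sprr1a (188 to 214), 406 CPM of Ptges (250 to 265), 137 CPM of Steap4 (97.8 to 102) and 48.6 CPM of Cxcr2 (9.54 to 12.5). Its values of S100a8, S100a9, Krt6b and Krt16 and its level of the IL-17 list did not exceed the critical value. A20KIKO mouse 1 had 465 CPM of Krt77 (302 to 317) and 44.2 CPM of Cacnb3 (58.3 to 60.7), A20KIKO mouse 2 had 236 CPM of Hsd17b7 (166 to 173), and the adipocyte list of A20KIKO mouse 3 stood at a level of 0 (0.68 to 0.76). A20WT mouse 1 had 185 CPM of Nr1d1 (249 to 253), 56.1 CPM of Aaas (48.4 to 49.4), 29.9 CPM of Steap4 (46 to 47.5) and 0.0115 CPM of Hdc (0.162 to 0.202). A20WT mouse 2 had 1.86 CPM of S100a9 (12.9 to 18), 0.036 CPM of Ly6c2 (0.151 to 0.184) and a level of -0.88 in the antimicrobial list (0.23 to 0.40). A20WT mouse 4 had 2.02 CPM of C1qa (1.12 to 1.17).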

How the results depend on the processing

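Of these settings the single lanes were chosen after the data were seen. The 576 changed genes (401 higher, 175 lower) became 374 under the stricter filter with 10328 genes tested (249 higher), 1133 with DESeq2 (729 and 404), 946 with weighted limma-voom (349 lower), 250 at an adjusted p under 0.01 (190 and 60) and 200 against a 1.5-fold change (175 and 25). Fewer genes tested and stricter thresholds account for part of this by construction, and otherwise the cause was not tested. Leaving out single libraries gave 348 to 619 genes, 254 to 443 of them higher and 92 to 181 lower. The remaining settings gave 527 to 636, and no changed gene reversed its sign in any setting. Tnfaip3 kept its direction and call in each of 22 settings, with a log2 change of 2.05 to 2.28. The number of lists passing, 28, became 0 with an estimated correlation and 23 to 30 without single libraries. Fry called 10 lists, 9 of them among the 28 and the other retinoid metabolism (fry adjusted p = 0.049). With the replicate number as a block 551 genes and 29 lists passed, and 460 of the 576 genes were kept. The labels do not say whether the numbers pair mice. In their deviations from the group means, same-numbered libraries correlated at -0.01 to 0.24, over 0.1 in 1 of 4 pairs. Libraries of unlike numbers correlated at -0.24 to 0.23, so a pairing was neither shown nor ruled out. Of 96 changed genes named here, 42 kept their call in every setting, and 37 lost it in a fit without a single library. Of 30 named genes that did not change, 8 values were called in another setting, 3 of Arhgdib, 3 of Hba-a1, 1 of Calr and 1 of Hdc. A further 6 values reversed: Cd3g at 0.01, 0.06 and 0.03 (without A20KIKO mouse 3, A20WT mouse 1 and A20WT mouse 3), and Krt6b, Sprr1a and Sprr2d without A20KIKO mouse 4, whose own values account for them. Without single libraries the log2 change ranged from -0.09 to 0.06 for Cd3g, from -0.42 to 5.30 for Krt6b, from -0.25 to 0.79 for Sprr1a and from -0.37 to 4.58 for Sprr2d.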

Other observations

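The tests of interferon genes and of the splits by list were chosen after the results were seen. Further genes were named here after their values were seen, and no list of nucleic acid sensors was tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the RNA sensors Ddx58 and Ifih1 rose from 11.3 ± 3.02 to 41.1 ± 13.2 CPM and from 10.9 ± 2.7 to 43.3 ± 16.4 CPM (SD, n = 4 each, adjusted p = 0.00272 for both), and Irf7, the transcription factor that amplifies type I interferon genes, rose 11.2-fold (adjusted p = 0.00126). Zbp1, a sensor of Z-form nucleic acid that can start necroptosis, went from 0.329 ± 0.241 to 17.7 ± 13.8 CPM (adjusted p = 0.0227, and 0.0547 to 0.0923 without any single A20WT mouse). Tmem173, which encodes STING, rose 3-fold (adjusted p = 0.0167, and 0.0516 to 0.0889 without A20KIKO mouse 1 or A20WT mouse 1, 2 or 3).

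Mcam, an adhesion molecule best known from endothelium and melanoma, rose from 1.43 ± 0.138 to 34.9 ± 14.7 CPM (SD, n = 4 each, log2 change 4.61, SE 0.32, edgeR adjusted p = 4.23e-05), and Vcam1, which binds leukocyte integrins, rose from 0.216 ± 0.207 to 6.59 ± 4.38 CPM (adjusted p = 0.00942, and 0.0679 without A20WT mouse 1). Both were named after their values were seen. The fixed keratinocyte adhesion and tight junction list had 0 of 25 members changed (camera adjusted p = 0.0984). The endothelial list did not pass, and its member Pecam1 had 1.24 ± 0.505 and 0.786 ± 0.219 CPM (adjusted p = 0.422). The melanocyte list passed as higher (camera adjusted p = 0.000252, and adjusted p = 0.425 with an estimated correlation), though 10 of the 35 splits of the libraries gave a p as small. It had levels of 1.15, 1.82, 0.79 and -0.02 in A20KIKO mice 1 to 4, where Mcam had 29.7, 50.7, 42.2 and 17 CPM, so the cells behind Mcam were not resolved. Of the EGF receptor ligands named here, Epgn rose 13.1-fold while Ereg and Btc fell, by 0.91 and 1.38 on the log2 scale. No list of these ligands was tested.

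Counts of interferon genes themselves were below the filter and were not tested. Of 21 interferon genes in the files, 7 had a count. Ifnl2, of the type III interferons, had 60, 2, 6 and 99 counts in A20KIKO mice 1 to 4 and 0, 1, 0 and 0 in A20WT mice 1 to 4. Ifnl3 had 10, 1, 8 and 55 counts, against 0 in each library labelled A20WT. Ifnb1 had 1, 2, 0 and 26 counts, against 0 in each library labelled A20WT. Ifng had 12 counts over the libraries labelled A20KIKO and 9 over those labelled A20WT, and Ifnk 3 and 12. Ifnl2 and Ifnl3 are close paralogs, so reads may be shared between them. At 0 interferon genes with at least 3 counts in each library labelled A20KIKO, these counts leave open which interferon, if any, the sheets made.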
